A study of Mus musculus with 9 samples.

How the data were processed

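RNA-seq libraries of ovarian tissue came from 9 samples in 3 groups of 3, taken from the labels as UT (no treatment), CTX (cyclophosphamide) and CAU (caulerpin). Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a SMARTer mRNA kit. The submitters' processing notes name HISAT2, Bowtie2, RSEM 1.3.1, DESeq2 1.44.0 and the mouse build GRCm38.p6, without their roles or order. The strand setting, the filters, the covariates and the annotation are not given in the sources used here.

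The only values used were those of the authors' deposited table of comparisons, with 1 line for each of 19517 genes. Per the file headers, it holds a log2 fold change, a DESeq2 p-value and a DESeq2 q-value for each of 3 pairs of groups. The log2 fold change was computed by the authors between groups, so it has no value per library. The p-value and q-value are those the authors deposited, and the q-value, called adjusted p here, was within 7.74e-05 of a Benjamini-Hochberg adjustment recomputed over the genes with a p-value in each comparison. Between 215 and 272 genes had blank values in a comparison and were left out of it. Sequencing depth per library is unknown here, so no interval or floor based on counts is given, and precision is described by the implied standard error.

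The headers do not state which group is the numerator. A column named for 2 groups was read as the second over the first. All 3 columns follow 1 convention, since CTX against UT and CAU against CTX added up to CAU against UT within 0.01 of a constant in 18772 of 18773 genes. The opposite reading would turn all signs together. With the reading used, 6 p53 targets were higher and none lower in the group given an alkylating drug.

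The implied standard error is the absolute log2 fold change divided by the absolute z of its 2-sided p-value, which assumes an unshrunken Wald test. The 95% intervals use it with a normal distribution. Genes with a deposited adjusted p under 0.05 are called changed. Because the table holds neither counts nor normalized values, the tests planned before the data were examined, a count test of all 9 libraries and a list test on log2 values per library, could not be run. The authors' DESeq2 result took the place of the first, and limma's camera test on the z values (cameraPR, limma 3.58.1 in R 4.3.3) that of the second.

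The list test used a preset correlation of 0.01 and a Benjamini-Hochberg adjustment over the lists with at least 5 measured genes. The 32 lists were fixed before the data were examined, and 4 further lists were written after the calls were seen, leaving out genes whose calls had been seen by then. Members were counted by the adjusted p over all genes and again adjusted over the list alone. Medians were also set against 10000 random lists of the same size matched on the implied standard error. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

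The genes named in the text follow a rule with 3 parts fixed before the data were examined. It takes the 5 largest rises and 5 largest falls among called genes in each comparison, up to 2 called members of each list (or 1 member where none passed), and 8 fixed genes. The rule's conditions on abundance and on non-overlapping libraries could not be applied. An implied standard error of at most 1 and a symbol that is not a predicted gene's replaced them for the first part, and the smallest implied standard error replaced the highest mean, both chosen after the data were seen. Genes outside the rule are said to be so.

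The shares of CTX-changed genes that moved back in CAU were set against 100 simulated draws each with CAU equal to CTX and with CAU equal to UT. Each group's share of the error was taken from the 3 implied standard errors of a gene, over 18773 genes with all 3 comparisons. UT had the largest share in 57.8% of these genes, CAU in 35.9% and CTX in 6.32%.

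The scripts were tested on simulated data with the real implied standard errors and 200 changed genes in each comparison. For CTX against UT, with 19260 genes, 35.6% of genes changed by 0.5 on the log2 scale were recovered, 47.8% of those changed by 1 and 75.0% of those changed by 2. For CAU against CTX, with 19245 genes, these were 31.2%, 46.7% and 72.4%. For CAU against UT, with 19302 genes, they were 25.0%, 54.7% and 67.7%. Between 3 and 5 unchanged genes were called in each. Of 60 unchanged lists, 0 were called with uncorrelated genes and 1 with a correlation of 0.1 within lists, and all 6 changed lists were called in the right direction in both. With ranks in place of z, 4 of the 60 unchanged lists were called at that correlation. The 60 were the same lists counted in each of the 3 comparisons, with the same shared error in each, so they are not independent cases. They held only genes with small implied standard errors, so these counts do not show how the test behaves for less precise lists.

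Alternatives were another threshold, a test against a fold of 1.5, genes with an implied standard error of at most 1, the median set to 0, z scaled to a robust spread of 1, larger preset correlations, ranks and matched random lists. Coordinates come from a RefSeq gene table of GRCm38.p6, the build the notes name, in which 19459 of the 19517 gene identifiers (99.7%) were found.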

Results

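Gene expression was measured by RNA-seq in ovarian tissue of female BALB/c nude mice, an athymic strain, that carried xenografts of MDA-MB-231, a human breast cancer cell line. The 9 libraries fell into 3 groups of 3. The UT group had no treatment, the CTX group had cyclophosphamide, an alkylating chemotherapy drug that is toxic to dividing cells, and the CAU group had caulerpin, an indole alkaloid of green algae of the genus Caulerpa. The labels of the CAU group name caulerpin alone and do not say whether cyclophosphamide was also given. The study's title concerns cyclophosphamide-induced ovarian dysfunction, macrophages and granulosa cell senescence, so the comparisons asked what differed between CTX and UT, between CAU and CTX, and between CAU and UT.

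The values used were those of the authors' deposited table, which gives a log2 fold change, a p-value and an adjusted p from DESeq2 for each of 19517 genes in each of the 3 comparisons. The sequencing depth of each library is unknown here, and no value per library was used, so neither the overlap between single ovaries nor the background in each untreated library was examined. Each log2 fold change is given with the standard error (SE) that its own p-value implies. Fold changes were read as the second group named in a column over the first, which the table does not state, and the opposite reading would turn every direction below. The labels number the libraries as replicate samples without naming separate mice, so the p-values measure the spread between these samples, which may be technical in part.

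In CTX ovaries, genes of macrophages and of antigen presentation were lower than in UT. Of 7 genes of MHC class II presentation, 6 fell and the median log2 fold change was -1.87. In the authors' deposited table, H2-Eb1 and H2-Aa, which encode MHC class II chains, fell by 2.20 and 2.17 on the log2 scale (SE 0.32 and 0.35, adjusted p = 1.93e-08 and 1.02e-06). Of 17 macrophage markers, 8 fell and none rose, and all 17 had negative log2 fold changes (median -0.96). The authors' deposited table gives -1.29 (SE 0.18, adjusted p = 1.16e-09) for Csf1r, the receptor for macrophage colony-stimulating factor, and -1.25 (SE 0.34, adjusted p = 0.0207) for Adgre1, which encodes the macrophage antigen F4/80.

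Adjusted over the list alone, 7 of the 7 MHC class II genes and 14 of the 17 macrophage markers fell. The complement gene C1qb was at -0.96 (SE 0.16, adjusted p = 4.13e-06) in the authors' deposited table, and Csf1, which encodes macrophage colony-stimulating factor itself, was at -0.45 (SE 0.10, adjusted p = 0.00256). Of 14 interferon response genes, 3 fell (7 adjusted over the list alone; median -0.54), among them Ifi44 at -1.18 (SE 0.19) and Oasl2 at -0.67 (SE 0.15) in the authors' deposited table. Both sets of polarisation markers were lower as lists, with none of 12 M1 genes and 1 of 13 M2 genes past the threshold for single genes. Adjusted over the list alone, 5 M1 and 2 M2 genes fell, and the list medians were -0.96 and -0.59. The M2 list had adjusted p = 0.0609 against matched random lists. Ccl22, the called M2 gene, had the imprecise value -6.43 (SE 1.70) in the authors' deposited table. Of 18 chemokines and cytokines, 1 fell (Csf1; 6 adjusted over the list alone) and all 18 were negative (median -0.55, list adjusted p = 3.88e-07, and adjusted p = 0.0604 against matched random lists).

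Markers of other white blood cells were lower as well. Of 11 T and NK cell genes, 2 fell (4 adjusted over the list alone; median -1.60), and in the authors' deposited table these were Ncr1, an activating receptor of NK cells, at -3.21 (SE 0.70, adjusted p = 0.00123) and Gzma, a cytotoxic granule protease, at -4.13 (SE 1.15, adjusted p = 0.0300). None of 10 neutrophil genes (median -1.39) and none of 6 B and plasma cell genes (median -0.92) passed singly or adjusted over the list alone. Their list tests gave adjusted p = 0.0158 and 0.0458 at the preset correlation of 0.01, and adjusted p = 0.0920 and 0.116 at a preset correlation of 0.10. The B and plasma cell list had adjusted p = 0.236 against matched random lists.

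Targets of p53, cell cycle genes and granulosa cell genes were higher in CTX than in UT. Of 22 p53 targets, 6 rose and none fell (10 rose adjusted over the list alone; median 0.33). In the authors' deposited table, Cdkn1a, the p21 inhibitor of cell cycle kinases, was 3.98-fold higher (log2 fold change 1.99, SE 0.32, adjusted p = 9.15e-07). Eda2r, a receptor gene induced by p53, was at 1.68 (SE 0.21, adjusted p = 3.8e-12) in the authors' deposited table. Of 27 cell cycle genes, 4 rose (23 adjusted over the list alone), and all 27 were positive with a median of 0.41. Top2a, a DNA topoisomerase of dividing cells, was at 0.62 (SE 0.15, adjusted p = 0.00909) and the checkpoint kinase gene Bub1 at 0.56 (SE 0.15, adjusted p = 0.0209) in the authors' deposited table.

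Of 16 granulosa cell genes, 4 rose (7 adjusted over the list alone; median 0.42). These included Inhbb, an inhibin and activin subunit, at 1.00 (SE 0.21, adjusted p = 0.000378) and Fst, which encodes follistatin, at 0.67 (SE 0.15, adjusted p = 0.00126) in the authors' deposited table. None of 16 DNA repair genes passed singly (2 rose adjusted over the list alone), and all 16 were positive (median 0.24, list adjusted p = 2.04e-07). The cholesterol synthesis list (median 0.17) and the theca list (median 0.13) each had adjusted p = 0.0218. These became adjusted p = 0.151 and 0.0952 at a preset correlation of 0.10, and the theca list had adjusted p = 0.0998 against matched random lists.

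Genes named in advance for the ovarian questions gave smaller or less precise differences. In the authors' deposited table, Amh, the anti-Müllerian hormone gene, was at 0.14 (SE 0.14), Fshr, the receptor for follicle-stimulating hormone, at 0.55 (SE 0.33), and Cyp19a1, the aromatase gene, at 1.08 (SE 0.52), none past the threshold. The oocyte growth factor gene Gdf9 was at 0.15 (SE 0.12), the senescence-related genes Cdkn2a and Lmnb1 at -0.60 (SE 1.14) and 0.46 (SE 0.16), in the authors' deposited table, also not past it. Of 20 genes linked to senescence and its secretory products, Cdkn1a rose and Igfbp3 fell, 16 were negative, and the list did not pass (median -0.58, adjusted p = 0.113, but adjusted p = 0.0487 with ranks in place of z). Igfbp3, which encodes a binding protein of insulin-like growth factors, was at -1.54 (SE 0.41, adjusted p = 0.0209) in the authors' deposited table.

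Markers of tissue that can come with an ovary moved in the same comparison. Surface epithelium genes were lower (1 of 9 fell, Upk3b; 3 adjusted over the list alone; median -1.27), as were 9 adipocyte genes as a list (median -1.36, adjusted p = 0.00819, and adjusted p = 0.0558 at a preset correlation of 0.10). The 10 oviduct epithelium genes were all negative (median -1.05), and the list did not pass at the main setting (adjusted p = 0.0528). It had adjusted p = 0.00912 with ranks in place of z and adjusted p = 0.0303 with the median of all genes set to 0, but adjusted p = 0.236 against matched random lists. The 12 immediate early genes, a sign of tissue handling, had a median of -0.28 (adjusted p = 0.0159, and adjusted p = 0.102 at a preset correlation of 0.10). The lists of steroid synthesis, oocyte, apoptosis, antioxidant, hypoxia, oxidative phosphorylation, extracellular matrix, luteal, endothelial, smooth muscle and skeletal muscle genes did not pass, with adjusted p from 0.0528 to 0.785. Against matched random lists, the steroid synthesis list was higher (median 0.25, adjusted p = 0.00138), and with ranks in place of z the oocyte list was (median 0.08, adjusted p = 0.0113). One hypoxia gene, Hif1a, rose by itself, at 0.28 (SE 0.07, adjusted p = 0.00546) in the authors' deposited table. The erythroid list had 4 measured genes, too few for the list test.

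By the adjusted p of the authors' deposited table, 249 of 19260 genes differed between CTX and UT, 91 higher and 158 lower. Of these, 75 differed at least 2-fold, 10 higher and 65 lower. Among called genes with an SE of at most 1 and a symbol that is not a predicted gene's, those with the largest rises were Ano3, of the anoctamin family, at 2.73 (SE 0.45) and Insyn2b at 2.51 (SE 0.51) in the authors' deposited table, followed by Cdkn1a, Eda2r and Grem1. The largest falls within that limit were of Ncr1, Ctse, H2-Ea, H2-Eb1 and H2-Aa, while Ccl22 and Gzma, with an SE above 1, lay lower. Of the 31 lists tested with limma's camera test on the implied z values, 18 passed, 6 higher and 12 lower, and 12 of them at a preset correlation of 0.10. An estimated correlation needs values per library, and none was computed. With the median of all genes set to 0, the calls were 290 with 156 higher and 134 lower, so which direction held most calls depended on that median, -0.03 on the log2 scale.

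**Figure D1:**
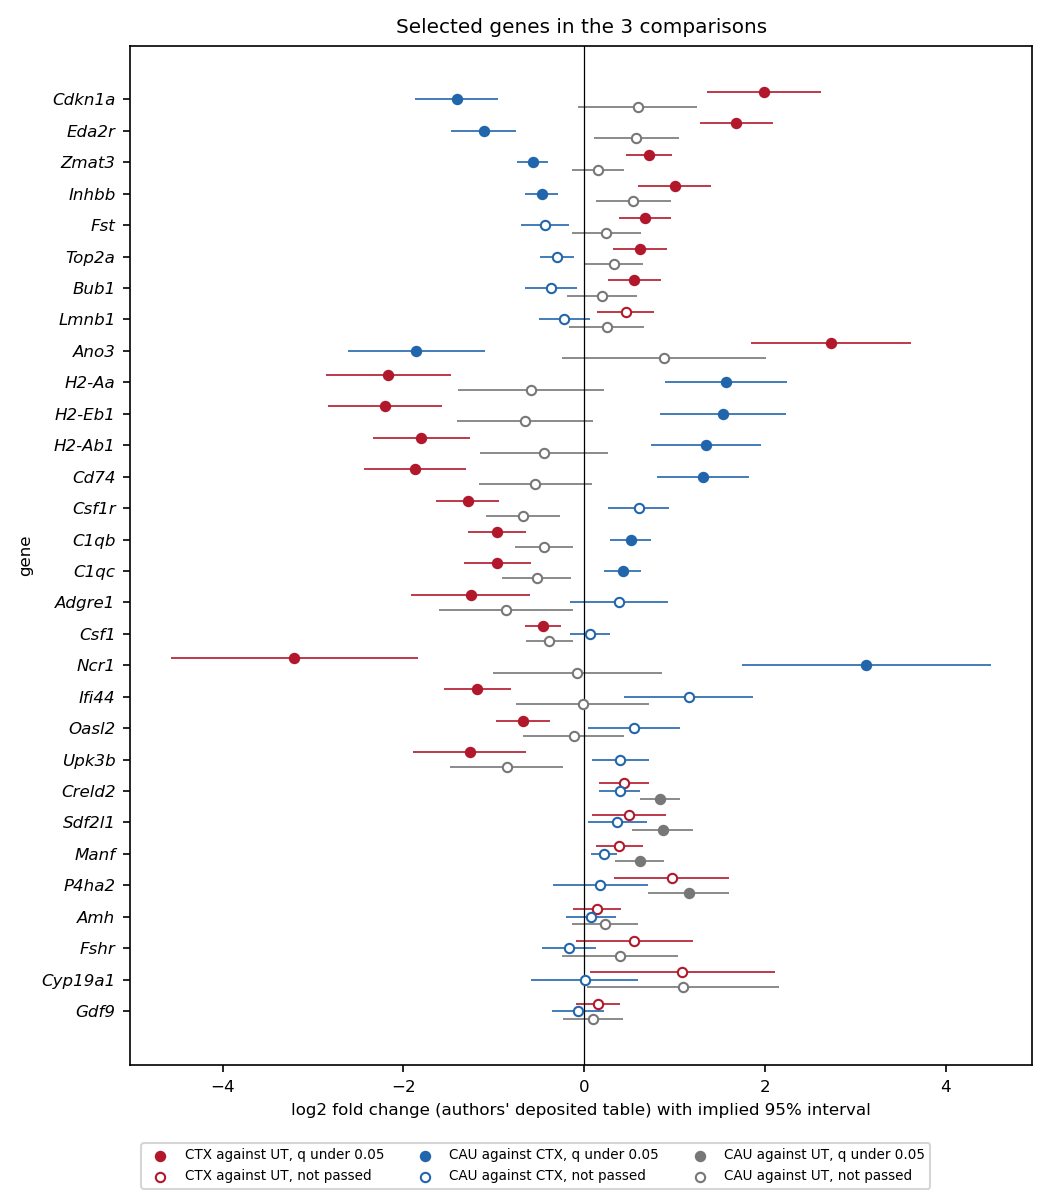
Log2 fold changes of 30 of the genes taken by the rule for named genes (vertical axis) in the 3 comparisons, from the authors' deposited table. Points are the authors' values, bars the 95% intervals implied by their p-values, and filled points have an adjusted p under 0.05. Cdkn1a lies at 1.99 in CTX against UT and -1.41 in CAU against CTX, and H2-Aa at -2.17 and 1.57.

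Between CAU and CTX, p53 targets were lower and MHC class II genes higher in CAU. Of 22 p53 targets, 5 fell and none rose (11 fell adjusted over the list alone; median -0.35). In the authors' deposited table, Cdkn1a was at -1.41 (SE 0.24, adjusted p = 6.35e-06), Eda2r at -1.11 (SE 0.18, adjusted p = 4.84e-06) and Zmat3, an RNA-binding p53 target, at -0.57 (SE 0.09, adjusted p = 9.04e-07). Of 7 MHC class II genes, 4 rose (6 adjusted over the list alone; median 1.35). H2-Aa was 2.97-fold higher in CAU (log2 fold change 1.57, SE 0.34, adjusted p = 0.00292) and Cd74, the invariant chain of MHC class II, 2.49-fold higher (1.32, SE 0.26, adjusted p = 0.000565) in the authors' deposited table.

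Of 17 macrophage markers, 2 rose (7 adjusted over the list alone; median 0.40), the complement genes C1qb at 0.51 (SE 0.12, adjusted p = 0.00630) and C1qc at 0.43 (SE 0.11, adjusted p = 0.0171) in the authors' deposited table. Adgre1 was at 0.39 (SE 0.28) in the authors' deposited table and did not pass. None of 14 interferon response genes passed, and 1 rose and 1 fell adjusted over the list alone. The interferon median was 0.52 (list adjusted p = 2.34e-05). The chemokine list was higher (median 0.30, adjusted p = 0.0154, but adjusted p = 0.160 at a preset correlation of 0.10 and adjusted p = 0.105 against matched random lists), and the M1 and M2 lists did not pass (adjusted p = 0.0985 and 0.0611). Of 11 T and NK cell genes, 2 rose (2 adjusted over the list alone; median 1.10). These were Gzma at 4.63 (SE 0.99) and Ncr1 at 3.12 (SE 0.70) in the authors' deposited table. The 10 neutrophil genes were higher as a list (median 2.47, median SE 1.14, adjusted p = 1.06e-06). None passed the threshold singly, and 1 was higher adjusted over the list alone. Of these genes 9 were positive, while Csf3r, the one with the smallest SE, was at -0.11 (SE 0.23) in the authors' deposited table.

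Granulosa and cell cycle genes were lower in CAU than in CTX by small amounts. Of 16 granulosa genes, Inhbb fell (2 adjusted over the list alone; median -0.13), at -0.47 (SE 0.09, adjusted p = 0.000565) in the authors' deposited table. None of 27 cell cycle genes passed (4 fell adjusted over the list alone), and 24 were negative (median -0.21, list adjusted p = 3.33e-12). The endothelial list was lower (median -0.15, adjusted p = 0.000588). The lists of oocyte (median -0.11), DNA repair (median -0.11) and cholesterol synthesis genes (median -0.09) were lower with adjusted p = 0.00826, 0.00768 and 0.00439. At a preset correlation of 0.10 these were adjusted p = 0.165, 0.101 and 0.0825. The steroid synthesis list was called lower (adjusted p = 0.00768, and adjusted p = 0.101 at a preset correlation of 0.10) although its median was 0.0046, its mean being -0.04. Against matched random lists that median was on the higher side, with adjusted p = 0.933. Amh was at 0.08 (SE 0.14), Fshr at -0.17 (SE 0.15), Cyp19a1 at 0.00 (SE 0.30), Gdf9 at -0.07 (SE 0.15), Cdkn2a at 0.33 (SE 1.12) and Lmnb1 at -0.22 (SE 0.15) in the authors' deposited table, none past the threshold.

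The largest single-gene rises in CAU against CTX were of many fold. Among genes with an SE of at most 1, Cyp26a1, a retinoic acid-degrading enzyme, was the highest at 74.1-fold in the authors' deposited table (log2 fold change 6.21, SE 0.98, adjusted p = 1e-06), followed by Gzma, Ecrg4 at 4.44 (SE 0.96), Moxd1 at 4.07 (SE 0.85) and Wfdc18 at 4.03 (SE 0.90). The 9 surface epithelium genes were all positive (median 0.78, 5 higher adjusted over the list alone, list adjusted p = 8.9e-07), as were the 10 oviduct epithelium genes (median 0.86, list adjusted p = 0.00228) and the 8 smooth muscle genes (median 0.19, list adjusted p = 0.000324). None of these genes passed singly, and the oviduct list had adjusted p = 0.109 against matched random lists. Adipocyte genes did not differ as a list (median -0.12, adjusted p = 0.646). The senescence, apoptosis, antioxidant, hypoxia, oxidative phosphorylation, extracellular matrix, theca, luteal, skeletal muscle, B cell and immediate early lists did not pass either, with adjusted p from 0.0623 to 0.890. Within the senescence list, Cdkn1a fell.

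By the adjusted p of the authors' deposited table, 85 of 19245 genes differed between CAU and CTX, 60 higher and 25 lower. Of the genes called higher, 42 were at least 4-fold higher, and 17 had an implied SE above 1. The median log2 fold change was 3.32 among genes called higher and -0.59 among those called lower. Of 31 lists, 17 passed, 9 higher and 8 lower, and 12 at a preset correlation of 0.10. The z values of this comparison were less spread than chance alone gives (robust spread 0.838), and 247 genes passed when z was scaled to a spread of 1.

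**Figure D2:**
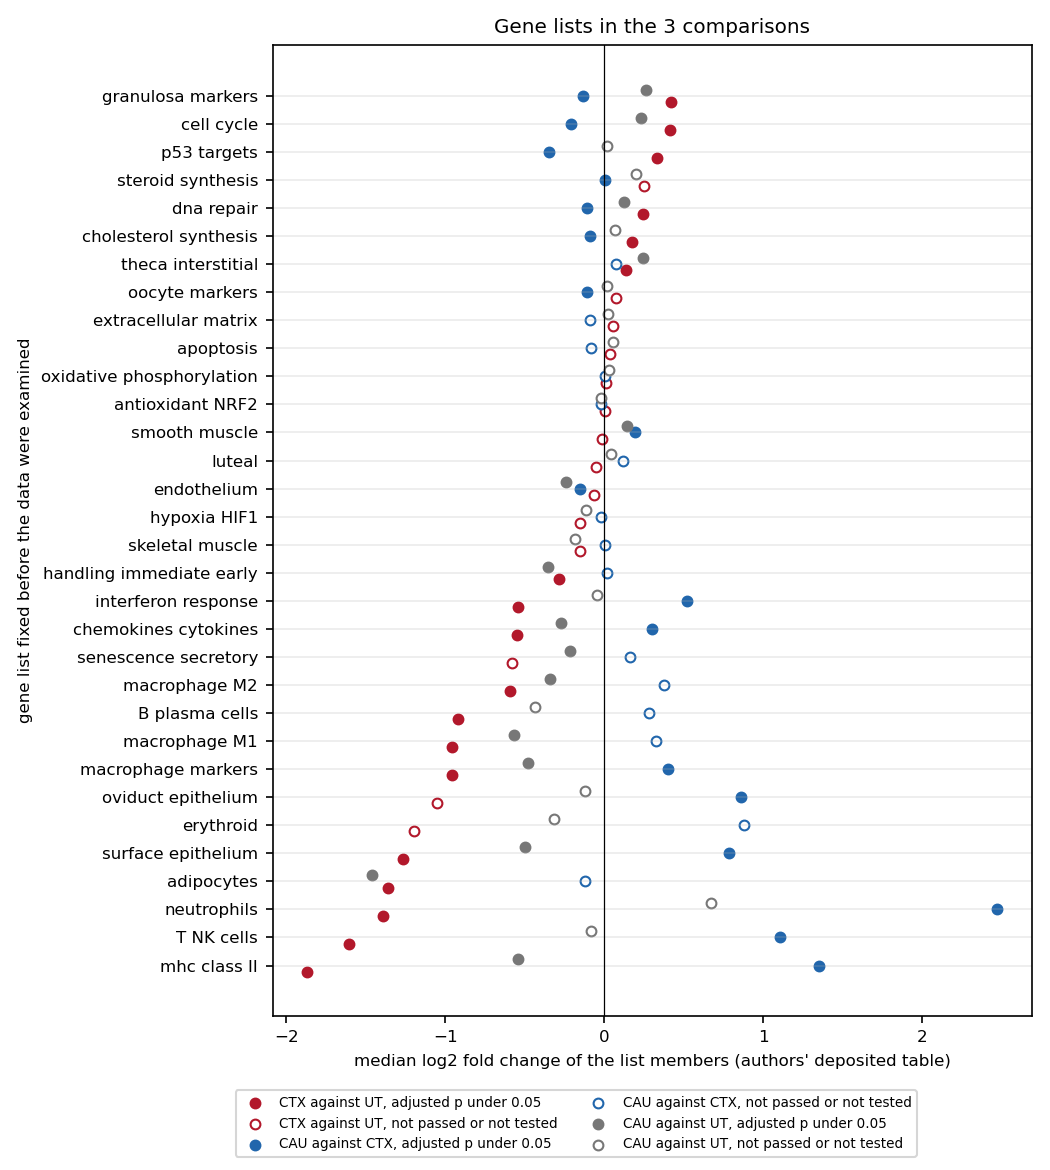
Median log2 fold change of the members of each of the 32 gene lists fixed in advance (vertical axis) in the 3 comparisons. Filled points have an adjusted p under 0.05 in the camera test at a preset correlation of 0.01. The MHC class II median is -1.87 in CTX against UT, 1.35 in CAU against CTX and -0.54 in CAU against UT.

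CAU ovaries differed from UT ovaries in few single genes. Of the 6 genes called higher, 5 encode proteins of the endoplasmic reticulum that take part in protein folding or its stress response, a count made after their values were seen. Creld2 was at 0.84 (SE 0.11, adjusted p = 1.63e-09), Sdf2l1 at 0.87 (SE 0.17, adjusted p = 0.00236), Pdia4, a disulfide isomerase, at 0.61 (SE 0.13, adjusted p = 0.00726) and Manf at 0.61 (SE 0.14, adjusted p = 0.0218) in the authors' deposited table. P4ha2, a collagen prolyl hydroxylase subunit, was at 1.16 (SE 0.23, adjusted p = 0.00236) in the authors' deposited table. Pdia6, the remaining gene called higher and named here after its value was seen, was at 0.45 in the authors' deposited table. The 4 genes called lower in the authors' deposited table were Ubtd1 at -2.45 (SE 0.28), Cish, a cytokine signalling inhibitor induced by STAT5, at -1.31 (SE 0.23), Kcnk2 at -0.88 (SE 0.20) and Nab2 at -0.46 (SE 0.10).

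No member of any fixed list passed singly in CAU against UT, while 15 of 31 lists did, 5 higher and 10 lower. Granulosa (median 0.27), cell cycle (median 0.23, 27 of 27 positive), DNA repair (median 0.13) and theca genes (median 0.24; 1 higher adjusted over the list alone) were higher, with list adjusted p = 2.53e-07, 5.51e-12, 0.000735 and 0.00421. Smooth muscle genes were higher too (median 0.15, adjusted p = 0.0274, but adjusted p = 0.104 at a preset correlation of 0.10 and adjusted p = 0.0922 against matched random lists). Macrophage markers were lower (5 adjusted over the list alone; median -0.48, list adjusted p = 3.49e-14), as were MHC class II genes (none over the list alone; median -0.54, list adjusted p = 0.000735). The M1 (median -0.57), M2 (median -0.34) and chemokine lists (median -0.27) were lower with adjusted p = 0.00243, 0.00427 and 5.03e-05, the M2 list having adjusted p = 0.0590 at a preset correlation of 0.10 and the M1 list adjusted p = 0.226 with ranks in place of z. Against matched random lists, the M2 and chemokine lists had adjusted p = 0.0775 and 0.0806. The median of p53 targets was 0.02 and that list did not pass (adjusted p = 0.285).

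Among the tissue markers, adipocyte (median -1.46), endothelial (median -0.24), surface epithelium (median -0.50) and immediate early genes (median -0.35) were lower in CAU than in UT, with list adjusted p = 3.43e-05, 2.53e-07, 0.00728 and 0.000855. The surface epithelium list had adjusted p = 0.0562 at a preset correlation of 0.10 and adjusted p = 0.0663 against matched random lists. The senescence list was lower (median -0.22, adjusted p = 0.0342, but adjusted p = 0.241 at a preset correlation of 0.10 and adjusted p = 0.253 against matched random lists). With the p53 list, 16 lists did not pass (adjusted p from 0.0560 to 0.872). Of these, the steroid synthesis (median 0.20) and neutrophil lists (median 0.67) were higher against matched random lists, each with adjusted p = 0.00895. Among the neutrophil genes 7 were positive and 3 negative. One of the latter, Csf3r, had the smallest SE and was at -0.70 (SE 0.30) in the authors' deposited table, not past the threshold. The B and plasma cell list (median -0.43) was lower with the median of all genes set to 0 (adjusted p = 0.0476). Of the genes named in advance, Cdkn1a was at 0.59 (SE 0.34), Adgre1 at -0.86 (SE 0.38), Amh at 0.23 (SE 0.19), Fshr at 0.39 (SE 0.33), Cyp19a1 at 1.10 (SE 0.54), Gdf9 at 0.10 (SE 0.17), Cdkn2a at -0.27 (SE 1.20) and Lmnb1 at 0.25 (SE 0.21) in the authors' deposited table, none past the threshold.

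By the adjusted p of the authors' deposited table, 10 of 19302 genes differed between CAU and UT, 6 higher and 4 lower. This comparison had the largest median implied SE, 0.238 against 0.209 for CTX against UT and 0.183 for CAU against CTX. Its z values were also less spread than chance alone gives (robust spread 0.712; 3.46% of genes had an unadjusted p under 0.05), and 251 genes passed when z was scaled to a spread of 1. The count of 10 therefore does not show that CAU and UT were alike.

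Most genes that differed between CTX and UT lay closer to UT in CAU. Of the 249 genes called, 237 (95.2%) had the opposite sign in CAU against CTX, and 32 (12.9%) were called in the opposite direction, while none was called in the same direction. The 32 comprised 14 genes higher in CTX, such as Cdkn1a, Eda2r, Ano3 and Inhbb, and 18 lower in CTX, such as H2-Aa, H2-Ea, Cd74, C1qb and Ncr1. The log2 fold change in CAU against UT was smaller than that in CTX against UT for 238 of the 249 genes, with a median ratio of 0.447, and 227 lay on the same side of UT in both groups.

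The comparisons share the CTX and UT libraries, which moves these figures without any effect of CAU. In 100 simulated draws with CAU equal to CTX, 56.6% of called genes had the opposite sign, 0.00535% were called in the opposite direction and the median ratio was 0.965. In 100 draws with CAU equal to UT, the figures were 98.8%, 55.1% and 0.0949, so these 3 observed figures lay between the simulated ones. The draws were unlike the data in that they called about 167 genes on average in CTX against UT, against 249 observed. They also used the full implied SE, while the z values of CAU against CTX were narrower than that (robust spread 0.838). The simulated figures are therefore rough bounds. Independent lists of these sizes would share 0.120 genes higher in CTX and lower in CAU and 0.499 genes of the other kind, against 14 and 18 observed. Over 15436 genes the covariance of the fold changes was -0.0765, against -0.0362 simulated with CAU equal to CTX, a difference of -0.0402, and -0.0492 simulated with CAU equal to UT. The observed covariance thus lay outside both simulated values, and no share of movement back is read from it. The simulation put effects only into called genes and drew genes independently, and the 3 libraries of a group could not be split here, so part of the excess may come from the shared libraries.

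**Figure D3:**
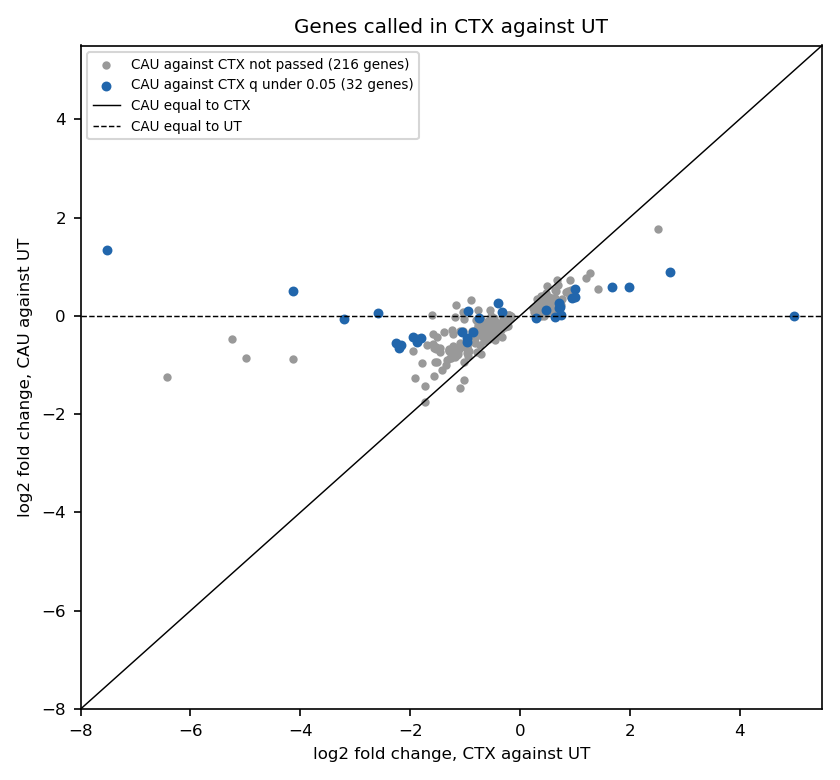
Log2 fold change in CAU against UT (vertical axis) over that in CTX against UT (horizontal axis) for 248 of the 249 genes called in CTX against UT, from the authors' deposited table. Blue points are the 32 genes also called in CAU against CTX, the solid line marks CAU equal to CTX and the dashed line CAU equal to UT. The median ratio of the vertical to the horizontal value is 0.447, and 1 gene below -8 is left out.

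Among the named genes located here, H2-Aa and H2-Eb1 lie near each other in the genome. In the GRCm38.p6 assembly, H2-Aa lies on chromosome 17 from 34282744 to 34287823 and H2-Eb1 on the same chromosome from 34305867 to 34316674, both protein-coding genes of the major histocompatibility complex. Cdkn1a lies on chromosome 17 from 29090979 to 29100722, Eda2r on chromosome X from 97333837 to 97377234 and Creld2 on chromosome 15 from 88819646 to 88826681. The H2 genes belong to a family of similar paralogs, and values for single members are uncertain where reads could be split between them. For H2-Q8, singled out after its value was seen, the authors' deposited table gives -22.1 in CTX against UT, while its other 2 comparisons add up to -8.07, so no fold is drawn from it.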

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

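All alternatives except the threshold of 0.01 were chosen after seeing the data. No paired analysis was possible because the table holds comparisons of whole groups and no value per library. For the same reason the planned count tests, other normalizations, filters on low counts, fits of 2 groups, omission of each replicate, fry, an estimated correlation and other splits of the samples were not run. The depth of the libraries is unknown, and how it limits the calls was not examined. At an adjusted p under 0.01, 117 genes passed in CTX against UT (249 at 0.05), 43 in CAU against CTX (85) and 7 in CAU against UT (10), and under 0.10 the CTX against UT count was 415, all by construction of the threshold. Against a fold of 1.5, 11, 14 and 1 genes passed, a stricter question by construction. With z scaled to a robust spread of 1, 247 genes passed in CAU against CTX and 251 in CAU against UT, since z was narrower than chance there (0.838 and 0.712), and 224 in CTX against UT. The share of CTX-changed genes with the opposite sign in CAU against CTX ranged from 93.3% at a threshold of 0.10 to 97.4% at 0.01 (95.2% at 0.05), and the share called in the opposite direction ranged from 9.40% to 14.5%. Counts of lists ranged from 12 to 21 in CTX against UT, 12 to 17 in CAU against CTX and 11 to 16 in CAU against UT. Of 50 list calls over the 3 comparisons, 20 were lost under at least 1 setting, 16 of the 50 under a camera setting and 12 against matched random lists, while 4 and 3 were gained. The steroid synthesis list in CAU against CTX turned from lower to the higher side against matched random lists (adjusted p = 0.933), where its median took the place of z. No other list and no named gene with a call changed direction. Of 52 calls of named genes, 12 were lost at the threshold of 0.01 and 40 against a fold of 1.5, none was lost in the other settings that kept the gene, and 6 were gained.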

Other observations

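All tests in this part were chosen after the results were seen, and the lists of ribosomal, interferon-gamma, epithelial, uterine and folding genes were written then.

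Most ribosomal protein genes had small log2 fold changes of the same sign in CTX against UT, and of the opposite sign in CAU against CTX. No list test was run on them, and these comparisons share the CTX libraries. Of 86 such genes, 18 fell and none rose in CTX against UT, 81 were negative and the median log2 fold change was -0.16, with 7 called when the median of all genes was set to 0. In CAU against CTX, 81 were positive with a median of 0.15. In CAU against UT, 49 were positive and 37 negative, with a median of 0.0070. No single gene was past the threshold in either.

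Genes inducible by interferon-gamma were lower in CTX than in UT and higher in CAU than in CTX as a list. Of 22 such genes that the fixed lists did not hold, 6 fell in CTX against UT and all 22 were negative (median -0.49, camera adjusted p = 2.38e-20). In CAU against CTX none passed singly and 20 were positive (median 0.36, camera adjusted p = 6.68e-07). In CAU against UT their median was -0.08 with 16 negative (camera adjusted p = 0.0466, and permutation p = 0.401 over matched random lists), while the MHC class II median was -0.54.

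MHC class II and macrophage genes were lower in CTX than in UT and higher in CAU than in CTX. A shift of the whole scale is argued against for the MHC class II fall in CTX against UT. The median of all genes there was -0.03, against -1.87 for MHC class II. With that median set to 0, 6 of the 7 genes still passed, a result that so small a change could hardly alter. This count was not made for macrophage genes or for the rise in CAU. As lists, MHC class II and macrophage genes kept their calls with the median set to 0, in CTX against UT and CAU against CTX. The median of all genes in CAU against CTX was 0.0040, so that setting could hardly alter calls there either. Adipose tissue carried along stays open for the rise in CAU. Adipocyte markers there had a median of -0.12 and a highest value of 0.00039, below the lowest MHC class II gene at 0.50. That comparison takes no account of their median implied standard error of 0.87. A first test that did, replaced after its result was seen, left adipose tissue open (median upper 95% bound of the markers 1.57, above the MHC class II median of 1.35). For the fall in CTX (adipocyte median -1.36 against -1.87 for MHC class II), adipose tissue stays open too. Against UT, adipocyte markers were as low in CAU (median -1.46, median implied standard error 1.07), where MHC class II was at -0.54. Tract tissue stays open, because the oviduct list decided nothing in CAU against UT (adjusted p = 0.799), and so does an untested effect of cyclophosphamide on white blood cells, the labels not saying whether CAU mice had that drug.

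Of the 60 genes called higher in CAU than in CTX, 42 were at least 4-fold higher. More reproductive tract epithelium in CAU than in CTX libraries may account for part of these rises. The 14 uterine and Hox genes, none of them called, had a median of 0.69. Against matched random lists this gave p = 0.0098, without regard to correlation between genes. The camera p of that list was 0.0160, and 0.0913 at a preset correlation of 0.10, and 17 epithelial junction genes, the list first used for this test, had a median of 1.53 and permutation p = 0.0002, with no single member of either list, nor of the surface epithelium and oviduct lists, past the threshold. Whether CAU gained such tissue or CTX lacked it is open: the junction genes were lower in CTX than in UT (median -1.34, 17 of 17 negative, permutation p = 0.0006) but the uterine and Hox genes did not pass there (median -0.39, permutation p = 0.572, camera adjusted p = 0.344), and neither list passed in CAU against UT (medians 0.16 and 0.10, camera adjusted p = 0.349 and 0.267). Imprecise values stay open, since 17 of the 42 genes had an implied standard error above 1, and so does an effect of caulerpin on ovarian epithelium, which was not tested apart from this.

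Targets of p53 were higher in CTX than in UT and lower in CAU than in CTX. A larger share of granulosa cells in CTX stays open: in CAU against CTX the p53 median lay 0.21 below the granulosa median, with 2-sided permutation p = 0.0356 over genes, which are not independent replicates, and 0.0533 adjusted over the 3 comparisons. A first test, of the same gap in CAU against UT, gave 0.25 (permutation p = 0.00666, and 0.0200 adjusted over the 3 comparisons). That test passed but was set aside after its result was seen, because the p53 median of 0.02 there covers 12 positive and 10 negative genes. A p53 response to cyclophosphamide was not tested apart from this, and the labels do not say whether CAU mice had that drug.

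A further hypothesis is that folding genes of the endoplasmic reticulum are higher in CAU than in UT as a class. The 32 folding and translocation genes outside the calls had a median of 0.25, 31 were positive and 10 rose adjusted over the list alone. Against matched random lists this gave p = 0.0002, the smallest these can give, without regard to correlation between genes. The same genes had medians of 0.18 in CTX against UT and 0.10 in CAU against CTX. In each of these, 28 were positive and p was 0.0002 against matched random lists. A shift from UT was thus seen in CTX too and was not particular to CAU. Both comparisons share the UT libraries, so a trait of those libraries cannot be told apart from a change in both groups.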
